A study of Mus musculus with 8 samples.

How the data were processed

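RNA-seq and ribosome profiling libraries came from KRPC-A cells, a line of pancreatic tumour cells derived from genetically engineered C57BL/6 mice. Gcn2 wild-type (WT) and Gcn2 knockout (KO) cells were placed for 1 h in amino-acid-replete or leucine-free medium. The 8 libraries make 8 groups (genotype, medium and assay) of 1 library each. There were no replicates. How the knockout was made, which exons it removed, and whether the cells were a clone or a pool are not given in the sources used here.

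Per the labels, cells were lysed in a buffer with 100 µg/mL cycloheximide and 1% Triton X-100, footprints were made with ribonuclease I, a linker was ligated, and the reverse-transcribed product was amplified by PCR. The labels name standard Illumina protocols for the RNA-seq libraries. Their strandedness and any selection of polyadenylated RNA are not given in the sources used here. The submitters' processing notes name cutadapt, STAR, featureCounts, Subread and the mouse build GRCm38. The deposited values are raw counts of reads per gene. Per the file headers, the counts were made with featureCounts 1.6.4 on the exons of Ensembl release 96 gene models, with no option for strand, multiply mapped reads or reads overlapping several genes. Counts therefore include reads in untranslated regions, so footprints on upstream open reading frames (uORFs) count toward the gene. Reads shared by near-identical copies or by overlapping genes are not counted.

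All 8 files list the same 55536 genes. Protein-coding reads numbered 41920840, 40792821, 37944264 and 31363754 in the RNA-seq libraries of WT replete, WT leucine-free, KO replete and KO leucine-free cells, and 9252255, 2425740, 6478334 and 4168476 in the footprint libraries. Symbols were joined by Ensembl identifier for 55450 of them (99.85%). Gene class came from the RefSeq table of GRCm38, patch 6, by symbol. It gave 21425 protein-coding genes and left 16869 without a class. Counts were normalised within each assay with trimmed mean of M-values (TMM) factors over protein-coding genes from edgeR 4.0.16 in R 4.3.3. The factors ran from 0.989 to 1.01 in RNA-seq and from 0.980 to 1.03 in the footprint libraries. Values per library are CPM, the gene's count over the scaled library total times 1e6. A protein-coding gene was measured when its mean count over the 4 libraries of an assay was at least 30, which left 10817 genes in RNA-seq and 9172 in footprints. Translation efficiency (TE) is the normalised footprint count over the normalised RNA count, for the 9100 genes measured in both assays. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

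The comparisons were leucine-free against replete medium in WT and in KO cells, KO against WT cells in each medium, and the WT minus KO difference of the leucine responses. Each was made in RNA-seq and in footprints, and the leucine comparisons also in TE. With 1 library per group no spread between cultures can be estimated, so no test across cultures and no p-value were computed. Ratios are log2 of normalised counts with a prior count of 0.5. Ratios of a pair of libraries have 95% exact (Clopper-Pearson) conditional binomial intervals, TE and WT minus KO values have 95% Wald intervals, and CPM values have exact Poisson intervals. A gene passed when its log2 ratio was at least 1 in size, a 2-fold difference, and its interval excluded 0. Where a gene had 0 counts in a library, the bound given sets that library at 3 counts. These 3 counts are the 1-sided 95% limit for a count of 0, so the end of the 2-sided exact interval, given beside the bound, is nearer 0. Intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules, and the differences have no check against replicates.

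Gene lists, comparisons, thresholds and other settings to compare were set before the data were examined. The 27 lists were ATF4 and CHOP targets, mRNAs with known uORF-dependent translation, cytosolic aminoacyl-tRNA synthetases, cytosolic ribosomal proteins, other 5' TOP mRNAs, lysosomal hydrolases, lysosomal membrane proteins and v-ATPase, autophagy, macropinocytosis and endosome traffic, endoplasmic reticulum chaperones, cholesterol synthesis, immediate early genes, S phase, G2 and mitosis, mitochondrially encoded proteins, nuclear-encoded oxidative phosphorylation, glycolysis, ribosome biogenesis, initiation factors, ribosome stalling and rescue, amino acid sensing and eIF2alpha kinases, branched-chain amino acid catabolism, amino acid transporters, and markers of pancreatic duct and epithelium, acinar cells, fibroblasts and mesenchyme, and immune and endothelial cells. For each list the median log2 ratio was computed with a counting interval from 1000 Poisson draws. It was ranked among the medians of 10000 random lists of the same size, matched in 20 bins of expression. That rank describes these libraries and is not a test across cultures. Which lists the text leads with was decided after their values were seen.

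The named genes followed a fixed rule. Eif2ak4 (Gcn2) and Atf4 were always named. In each comparison the candidates were the 10 higher and the 10 lower passing genes whose interval end nearest 0 was largest in size. From each list came up to 4 members in the direction of the median (6 for ATF4 and CHOP targets, ribosomal proteins and hydrolases) and up to 2 in the other. Olfactory, predicted and non-coding genes were not named. The results of some genes that the rule gave are not reported here.

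The procedure was tested on simulated data with 200 changed genes. With counting noise alone, 3 of 10617 unchanged genes passed for RNA-seq in WT cells, 15 of 8972 for footprints and 24 of 8900 for TE. Genes changed 4-fold passed in 100%, 98.5% and 98.5% of cases, and genes changed 2-fold in 56.7%, 64.2% and 56.7%. With an added coefficient of variation of 0.2, drawn separately for each library of either assay, 214, 284 and 952 unchanged genes passed. These are more than the 184, 137 and 264 genes that passed in the data. For KO cells 227, 223 and 916 unchanged genes passed, against 343, 196 and 273 in the data, and for WT minus KO 1055, 1030 and 2163, against 504, 429 and 717. The value of 0.2 was chosen and not estimated from these libraries. Separate draws cannot cancel in TE, as a spread shared by both assays would. The simulated counts therefore do not tell how many of the passing genes are noise. Among RNA-seq genes with mean counts from 30 to 60, the robust SD of the WT log2 ratios was 0.72, 2.24 times the counting SD, and above 3000 it was 0.20, 7.93 times. For KO against WT RNA in leucine-free medium the SD above 3000 was 11.5 times the counting SD, so the intervals of abundant genes are far narrower than the spread among genes of like count.

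The other settings were DESeq2 1.42.0 size factors, total counts, mean counts of at least 10 or 100 and no filter beyond 1 count, a 1.5-fold rule, a prior count of 5, and all genes in place of protein-coding ones. DESeq2 factors moved the median of all genes by at most 0.01 log2 and total counts by at most 0.08. Added after the data were seen were a rule of 3 robust SDs of the 300 genes of nearest mean count, removal of a running median over exonic length, footprint genes that also have RNA, thinning of the other footprint libraries to the protein-coding read total of the WT leucine-free one, and random lists matched also on length. A planned analysis of leucine codons was not run, since no coding sequences were used here. Read-level data, footprint lengths and reading frames were not used here.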

Results

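Messenger RNA and ribosome footprints were counted in Gcn2 WT and Gcn2 KO pancreatic tumour cells after 1 h with or without leucine. GCN2 is a kinase that is activated when uncharged transfer RNA accumulates. It phosphorylates the initiation factor eIF2alpha, which lowers general initiation and favours translation of the transcription factor ATF4. Ribosome footprints are the mRNA fragments that ribosomes protect from nuclease, so their counts follow how many ribosomes sit on an mRNA. Normalised counts are relative within a library, so higher and lower mean relative to the other genes of that library. A general change in translation or RNA amount would not show in them. The 4 RNA-seq libraries were WT replete with 57455985 counted reads, WT leucine-free with 60680169, KO replete with 59132491 and KO leucine-free with 49136610. The footprint libraries in the same order held 9993211, 2671491, 6921265 and 4563018 reads, fewest in WT leucine-free cells. Protein-coding genes took 73.0%, 67.2%, 64.2% and 63.8% of the RNA reads and 92.6%, 90.8%, 93.6% and 91.4% of the footprints. Mitochondrial ribosomal RNA took 24.7%, 30.5%, 33.3% and 33.6% of the RNA reads. Every group is 1 library, so each ratio compares a pair of libraries and not the conditions they stand for.

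Eif2ak4, the gene that encodes GCN2, had fewer reads in both KO media and both assays. The gene (ENSMUSG00000005102) lies on chromosome 2, GRCm38 positions 118388618 to 118475234, plus strand. In RNA-seq it had 85.7 normalised CPM (95% interval 82.9 to 88.5) in WT replete, 69.7 (67.1 to 72.3) in WT leucine-free, 13.6 (12.5 to 14.8) in KO replete and 16.7 (15.3 to 18.2) in KO leucine-free cells. Its footprints were 60.2 CPM (55.3 to 65.5), 65.2 (55.4 to 76.3), 7.26 (5.33 to 9.66) and 16.2 (12.6 to 20.5) in the same order. KO RNA was thus 15.9% of WT in replete and 24.0% in leucine-free medium, and KO footprints were 12.2% and 25%. Its leucine-free footprint ratio in KO cells was 1.15 (0.61 to 1.73), and the KO footprint count was 47 in replete and 70 in leucine-free medium. The exons deleted are not given in the sources used here, so a low count alone does not show that the protein was absent.

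Atf4 encodes the transcription factor whose translation depends on uORFs and rises when eIF2alpha is phosphorylated. In WT cells its footprints were 172 CPM (164 to 181) in replete and 527 (498 to 557) in leucine-free medium. In KO cells they were 199 (189 to 211) and 212 (198 to 226). Its RNA was 261 and 486 CPM in WT cells and 465 and 528 in KO cells. Exonic counts include footprints on the Atf4 uORFs, so they do not measure the ATF4 coding sequence alone.

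**Figure D1:**
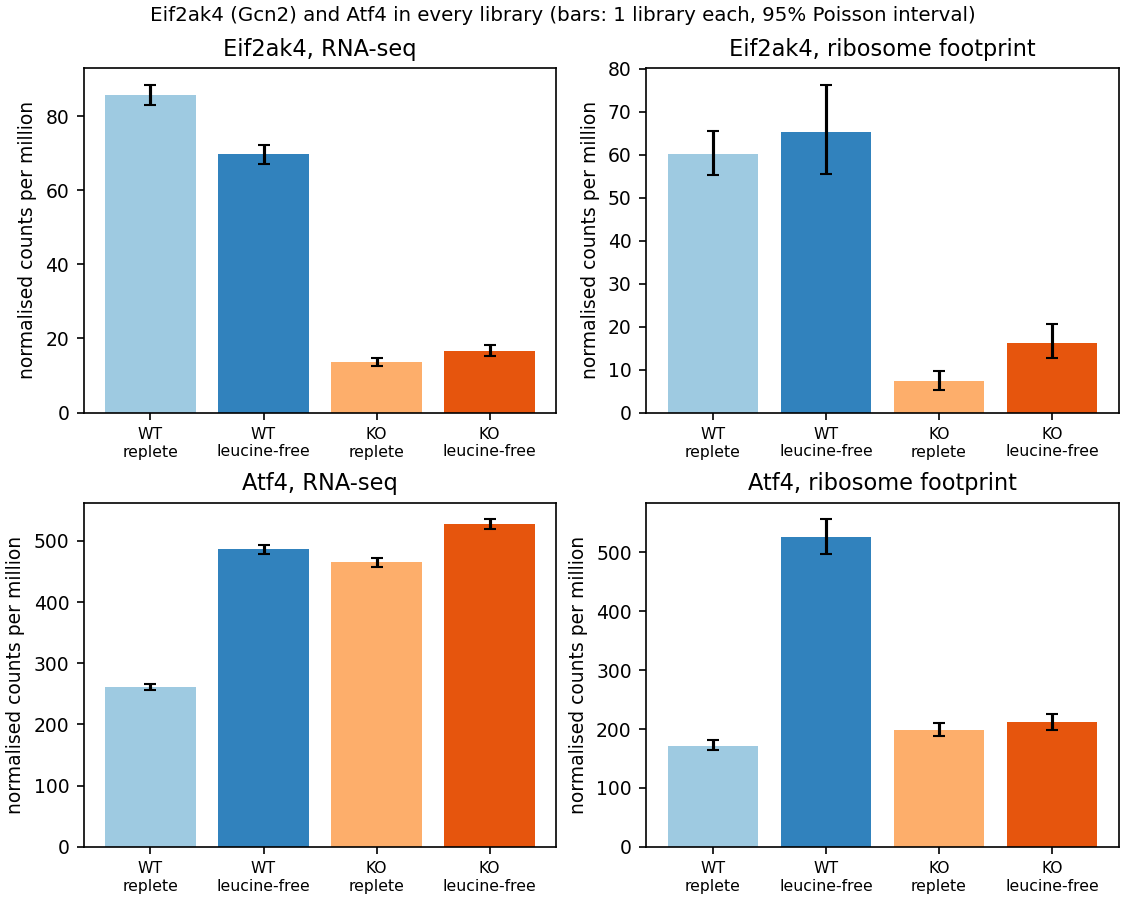
Normalised CPM of Eif2ak4 and Atf4 in each library, RNA-seq and ribosome footprints apart, with 95% Poisson intervals as bars. Eif2ak4 is lower in every KO library, and Atf4 footprints stand at 527 CPM in WT leucine-free cells against 172 to 212 in the other libraries.

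The response of WT cells to leucine-free medium shows what was higher or lower after 1 h with Gcn2 intact. Footprints on mRNAs with uORF-dependent translation were higher without leucine, as were RNA and footprints of ATF4 and CHOP targets and of immediate early genes. The uORF list and the list of ATF4 and CHOP targets share Atf5, Ddit3, Ppp1r15a and Cebpb, so in every comparison they are not separate results. Footprints on ribosomal protein mRNAs and other 5' TOP mRNAs were lower. The median uORF mRNA had a footprint log2 ratio of 0.97 (0.68 to 1.24) and an RNA log2 ratio of -0.01, and 10 of 11 measured members were above 0 in footprints. The median ribosomal protein mRNA had a footprint log2 ratio of -0.46 (-0.52 to -0.38), with 51 of 63 members below 0. In footprints 81 genes passed as higher and 56 as lower, in RNA-seq 91 and 93, and in TE 104 and 160.

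Among uORF mRNAs in WT cells, 5 passed as higher in footprints and none as lower. Ddit3, which encodes the stress transcription factor CHOP, had the highest ratio at 3.63 (2.96 to 4.46), from 21 counts in replete medium to 71 in leucine-free medium. Ppp1r15a, which encodes GADD34, a regulatory subunit of the phosphatase that reverses eIF2alpha phosphorylation, had 1.91 (1.47 to 2.37). Atf4 had 1.61 (1.51 to 1.72) and Ifrd1, another uORF mRNA, 1.57 (1.43 to 1.70). The synthetase mRNA Eprs was the exception at -0.19. The list's TE median was 0.87 (0.68 to 1.12), above all 10000 random lists. With the length trend removed it was 1.17, and with mean counts of at least 100 the footprint median was 0.48.

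ATF4 and CHOP targets, genes for amino acid synthesis, amino acid uptake and stress responses, had a median of 0.30 (0.20 to 0.33) in RNA and 0.29 (0.21 to 0.42) in footprints of WT cells. Both lay above all 10000 random lists. In each assay 6 members passed as higher, and Vldlr, a lipoprotein receptor gene with RNA counts of 64 and 14, was the only one that passed as lower, in RNA. Chac1, a glutathione-degrading enzyme, had 2.43 in RNA (2.21 to 2.66) and 2.89 in footprints (2.48 to 3.34). Atf3, a stress-induced transcription factor, had 1.95 in footprints, and Herpud1, which takes part in degradation of endoplasmic reticulum proteins, 1.04 and 1.17 in RNA and footprints. Trib3, a pseudokinase induced by CHOP, had 1.39 in RNA, and Eif4ebp1, an inhibitor of cap-dependent initiation, 1.14. Phgdh and Eif4ebp1 were below 0 in footprints, at -0.34 and -0.35. With mean counts of at least 100 the footprint median was 0.08. The list's TE median was 0.13, and 0.27 with the length trend removed.

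Ribosomal protein mRNAs belong to the 5' TOP class, whose translation depends on mTORC1. In WT cells 6 of 63 passed as lower in footprints and 1 as higher. Rpl35a stood at -1.24 (-1.45 to -1.05), Rpl13a at -1.12 and Rps15a at -1.10, while Rpl39 was at 1.13. Their RNA was on the high side, with a median of 0.30, which was 0.09 with the length trend removed. RNA ratios in this comparison fell with exonic length, with a Spearman rho of -0.38 across genes and a median of 0.40 for the 178 genes under 1000 nt. The TE median of ribosomal protein mRNAs was -0.78 (-0.84 to -0.67), below every random list, and -0.50 with the length trend removed. Other 5' TOP mRNAs had a footprint median of -0.34 with 21 of 22 below 0 and a TE median of -0.63 with 22 of 22 below 0. Pabpc1, the cytoplasmic poly(A)-binding protein, had the lowest footprint ratio of the named genes at -2.30 (-2.50 to -2.12), from 4436 counts to 237. Eef1b2, a subunit of elongation factor 1, stood at -1.06.

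Immediate early genes, which are transcribed within minutes of growth or stress signals, had WT medians of 0.76 (0.67 to 0.80) in RNA and 0.89 in footprints, with 9 and 12 of 27 members passing as higher. Fos had 2.16 in RNA and 2.83 in footprints, Egr2 1.86 and 2.15, and Egr1 1.52 and 2.06. Histone genes made up 6 of the 10 leading RNA genes, among them Hist1h4n at 2.15 (2.06 to 2.24) and Hist1h1b at 1.61. Footprints of Fuca1, a lysosomal fucosidase, stood at -1.80, of Pcbp2, an RNA-binding protein, at -1.50, and of Fth1, the ferritin heavy chain, at -1.43. Fuca1 footprint counts were 1018 in WT replete, 77 in WT leucine-free, 118 in KO replete and 144 in KO leucine-free cells. Its KO against WT footprint ratio in replete medium was -2.62, so its WT ratio rests largely on the WT replete library. Tlx3 and Nova2, with Nova2 at 1.88, were among the leading footprint genes but had almost no RNA, with 0 RNA counts for Tlx3 in every library and at most 14 for Nova2. Reads mapping from other sequences were not ruled out for such genes, here or in the other comparisons. The leading lower RNA genes had few counts, such as Itgb1bp2 with 63 and 8 and Pycard, an inflammasome adaptor, with 164 and 42. Of the genes that passed, 66 in RNA, 91 in footprints and 98 in TE also lay beyond 3 SDs of genes of like count. With mean counts of at least 100, RNA-seq gave 53 higher and 12 lower genes, footprints 38 and 23, and TE 25 and 94. The split turned with the setting, to 67 higher and 109 lower in RNA and 108 and 92 in TE with the length trend removed, and to 329 and 564 in RNA and 374 and 237 in TE with no filter beyond 1 count.

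The response of KO cells shows what leucine-free medium was accompanied by when Gcn2 was disrupted. Immediate early genes were far higher without leucine, in RNA and in footprints, and led both rankings. uORF mRNAs and ATF4 and CHOP targets had medians near 0, and so did ribosomal protein mRNAs. The immediate early median was 2.07 (2.04 to 2.16) in RNA, with 27 of 27 members above 0 and 20 passing as higher. In footprints it was 1.88 (1.82 to 2.14), with 19 of 27 passing as higher. In RNA-seq 191 genes passed as higher and 152 as lower, in footprints 140 and 56, and in TE 143 and 130.

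Btg2, an antiproliferative early gene, had RNA counts of 1216 and 25232 in KO replete and leucine-free cells, a log2 ratio of 4.68 (4.60 to 4.76), and 3.81 in footprints. Fos stood at 4.11 in RNA (3.96 to 4.27) and 4.26 in footprints. Zfp36, which encodes an mRNA decay factor, stood at 3.59 and 3.61. Egr2 stood at 3.44 in RNA, and Dusp1, a MAP kinase phosphatase, at 3.53 in footprints. Jun had a footprint ratio of 2.72 and Nr4a1, an orphan nuclear receptor, 2.76. Outside the list, Egr4 had an RNA ratio of 4.38, Arc 3.61 and the cytokine gene Il11 4.29. TE of the list was slightly below 0, at -0.25.

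Atf4 footprints in KO cells had a log2 ratio of 0.09 (-0.04 to 0.21). The uORF list had a footprint median of 0.09 (-0.08 to 0.26), which was -0.08 with mean counts of at least 100, and a TE median of -0.10. Ddit3 was the one uORF mRNA that passed as higher in KO footprints, at 3.61 (2.32 to 5.74), from 4 counts to 37, and Cebpb had 0.72. Ppp1r15b, which encodes the constitutive subunit of the eIF2alpha phosphatase, had a TE ratio of -1.11 (-1.33 to -0.90). ATF4 and CHOP targets had medians of -0.01 in RNA and -0.06 (-0.24 to 0.01) in footprints. Among them Atf3, which is also an early stress gene, had 3.92 in RNA and 2.74 in footprints. Ddit4, an inhibitor of mTORC1, had 1.14 in RNA. The amino acid genes Aldh18a1 at -0.50, Psat1 at -0.39 and Asns at -0.36 were below 0 in footprints.

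Ribosomal protein mRNAs in KO cells had a footprint median of 0.00 (-0.12 to 0.08), with 32 members above and 31 below 0. The median was 0.08 with mean counts of at least 10 and -0.13 with mean counts of at least 100. Their TE median was -0.07, and 0.01 with total counts. Pabpc1 footprints were at 0.38 in KO cells, and other 5' TOP mRNAs had a footprint median of -0.24, against -0.13 for random lists of like expression. Lysosomal hydrolases, which digest scavenged protein, had a footprint median of -0.19 with 33 of 43 below 0 and a TE median of -0.34, below every random list. Psap, the precursor of the saposins, was at -0.58 in footprints, Tpp1, a lysosomal peptidase, at -0.64, and the protease gene Ctsb at -0.48. Footprints of Rbm3, a cold-inducible RNA-binding protein, were at -1.56, of the neuronal tubulin gene Tubb3 at -1.47 and of Eif5, the GTPase-activating factor of initiation, at -1.19. Footprints of Nhlrc1 at -5.42 and Vsig8 at -4.79 had the lowest ratios, but these genes had no RNA or almost none. Their KO replete footprint counts were 858 and 2838, against 13 and 68 in KO leucine-free cells. WT replete cells had 18 and 67, and WT leucine-free cells 13 and 34. The ratios thus rest on the KO replete library alone.

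Lower RNA genes in KO cells were again of low count. Dkk2, a Wnt antagonist, had 57 counts in replete and 0 in leucine-free medium, at least 15.4-fold lower with the latter set at 3 counts, with a 95% interval of the log2 ratio that ends at -3.60, and Rab4a, a GTPase of endosome recycling, stood at -2.33 (-3.02 to -1.73). Of the genes that passed, 110 in RNA, 144 in footprints and 72 in TE also lay beyond 3 SDs of genes of like count, and RNA-seq gave 97 higher and 38 lower genes with mean counts of at least 100 but 662 and 693 with no filter beyond 1 count. The split of the TE genes depended on the scaling, with 52.4% higher under TMM and 67.1% (192 higher and 94 lower) with total counts, and on the filter, with 46 higher and 63 lower at mean counts of at least 100.

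**Figure D2:**
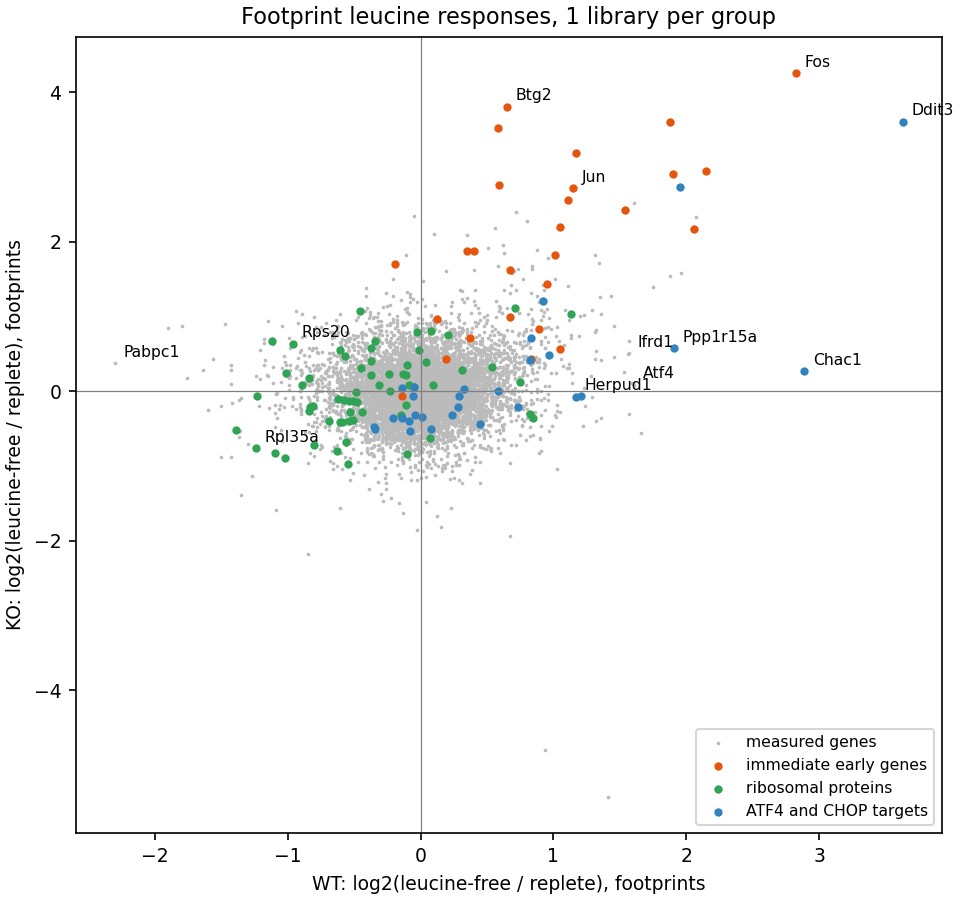
Each point is a gene measured in ribosome footprints, with the log2 ratio of leucine-free to replete medium in WT cells on the x axis and in KO cells on the y axis. Immediate early genes (median 0.89 in WT, 1.88 in KO), ribosomal proteins (-0.46 and 0.00) and ATF4 and CHOP targets (0.29 and -0.06) are coloured.

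The difference between the leucine responses of WT and KO cells addresses how far the response went with Gcn2. uORF mRNAs and ATF4 and CHOP targets had the higher footprint response in WT cells. Immediate early genes had the higher response in KO cells, and ribosomal protein mRNAs had the lower response in WT cells. These differences rest on 4 libraries each and were not tested across cultures. The WT minus KO footprint median was 0.72 (0.40 to 1.09) for uORF mRNAs, with 11 of 11 above 0. It was 0.35 (0.25 to 0.46) for ATF4 and CHOP targets, with 24 of 29 above 0. It was -0.38 (-0.46 to -0.31) for ribosomal proteins and -0.95 (-1.17 to -0.82) for immediate early genes.

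Atf4 had a WT minus KO difference of 1.53 (1.36 to 1.69) in footprints, 0.71 in RNA and 0.81 in TE. Ifrd1 had 1.06 in footprints, Ppp1r15b 1.13 and Ibtk 1.37, while Ddit3 had 0.01. The KO response of Ddit3 rests on 4 footprint counts in replete and 37 in leucine-free medium, so a difference either way stays open. Chac1 had 2.70 in RNA and 2.62 in footprints, and Herpud1 1.33 and 1.25. Slc38a2, a neutral amino acid transporter, had 0.88 in footprints and 1.02 in TE. Atf3 went the other way at -2.33 in RNA. The immediate early list had an RNA median of -1.36 with 17 of 27 members passing as lower, including Btg2 at -3.64 (-3.80 to -3.48), Jun at -2.32 and Dusp1 at -2.40. Ptgs2, the inducible cyclooxygenase, had -2.06.

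The TE median of ribosomal protein mRNAs was -0.57 (-0.70 to -0.51) in WT minus KO, with 14 of 62 passing as lower and 2 as higher, and it was -0.44 with the length trend removed. Rps20 had -1.91 and Rpl32 -1.73, while Rpl6 had 1.09. Other 5' TOP mRNAs had -0.29 in TE and -0.06 in footprints. Pabpc1 had -2.68 in footprints and -3.25 (-3.46 to -3.05) in TE, and Tpt1 -1.73 and -1.50. Lysosomal hydrolases had 0.17 in footprints, with Gaa, the acid glucosidase, at 0.82 and Fuca1 at -2.67. The Fuca1 value rests largely on its high count in the single WT replete footprint library. Footprints of Gapdh had 1.67, of Odc1, the first enzyme of polyamine synthesis, -2.10, and of the cytoskeletal genes Plec 1.73 and Dync1h1 1.72. Nhlrc1 at 6.83 and Vsig8 at 5.72 led the footprint ranking on genes with no RNA or almost none. Both values rest on high footprint counts in the single KO replete library. In footprints 151 genes passed as higher and 278 as lower, in RNA-seq 239 and 265, and in TE 312 and 405. Beyond 3 SDs of genes of like count there were 27 and 107 in footprints, 27 and 57 in RNA-seq, and 29 and 63 in TE.

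**Figure D3:**
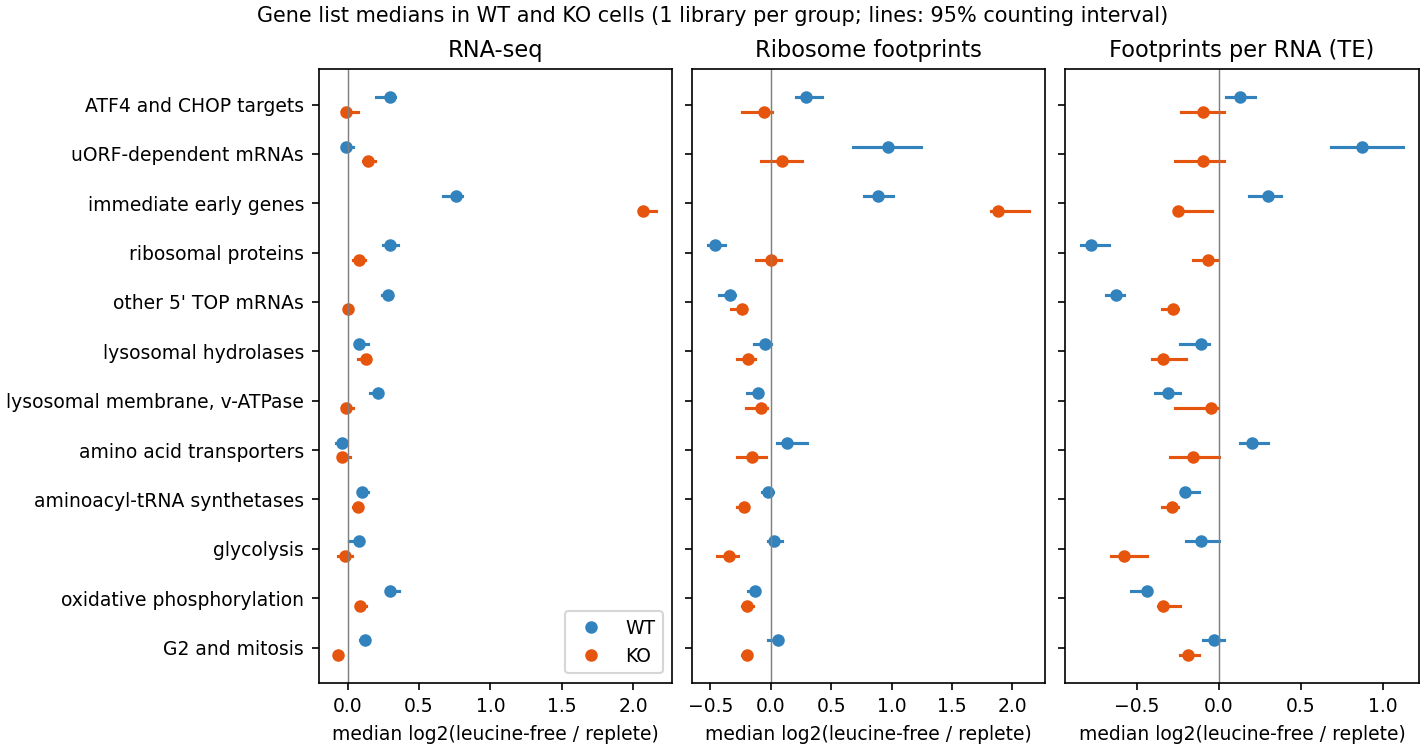
Median log2 ratio of leucine-free to replete medium for 12 gene lists in WT and KO cells, in RNA-seq, ribosome footprints and TE, with bars for the 95% counting interval of each median. In footprints uORF mRNAs stand at 0.97 in WT and 0.09 in KO, and immediate early genes at 0.89 and 1.88.

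KO against WT cells in replete medium asks what differed between the populations before leucine was removed. Besides Eif2ak4, a set of genes was almost silent in KO cells, and immediate early genes were higher in KO cells. Grb10, an adaptor that restrains insulin receptor signalling, had RNA counts of 5441 in WT and 42 in KO cells, a log2 ratio of -6.87 (-7.36 to -6.45), and -6.68 (-8.26 to -5.68) in footprints. Xdh, xanthine dehydrogenase, had 439 RNA counts in WT and 0 in KO cells, at least 133-fold lower with KO set at 3 counts, with a 95% interval of the log2 ratio that ends at -6.76, and a footprint ratio of -5.57 (-8.11 to -4.25).

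In RNA-seq 471 genes passed as higher in KO cells and 271 as lower, and in footprints 198 and 76. Gas7 had an RNA ratio of -8.18, with 2066 counts in WT and 6 in KO cells, but its footprint counts were 479 and 419, for which reads mapping from other sequences were not ruled out. Cyp26b1, which degrades retinoic acid, had -4.48 in RNA. Gprc5c, an orphan receptor gene, had 5.51 (4.42 to 7.30) in RNA and the integrin gene Itgb3 4.57. In footprints Hkdc1, a hexokinase-like gene, had 3.81 and Tppp3 3.27, and Smarca1, a chromatin remodelling ATPase gene, had -2.93. Vsig8 at 5.87 and Nhlrc1 at 6.00 headed the footprint ranking with no RNA or almost none. Both again rest on high footprint counts in the single KO replete library. Immediate early genes had medians of 0.93 in RNA and 0.82 in footprints, with 12 and 10 of 27 passing as higher, such as Junb at 2.10 in RNA and Nr4a1 at 2.26 in footprints. Cholesterol synthesis genes had smaller medians of 0.41 in RNA and 0.37 in footprints, where 20 of 21 were above 0, but 0 of 22 passed in RNA and 0 of 21 in footprints.

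ATF4 and CHOP targets were slightly lower in KO cells in replete medium, with medians of -0.20 in RNA and -0.23 in footprints. Stc2 had -2.58 and the cystine transporter gene Slc7a11 -1.37 in RNA. Phgdh, the first enzyme of serine synthesis, had 1.25, and Atf4 had 0.84 in RNA and 0.21 in footprints. Ribosomal proteins had 0.14 in RNA and -0.07 in footprints. Genes of chromosome X had a median of -0.42 in RNA and -0.52 in footprints, and chromosomes 3 and 5 had -0.26 and -0.20 in RNA and -0.29 and -0.21 in footprints. These chromosomes were singled out after their values were seen. They held 84 of the 271 genes lower in KO RNA (31%), against 14.3% of all genes. Beyond 3 SDs of genes of like count there were 235 genes in RNA and 169 in footprints, and 82 higher and 31 lower genes passed in footprints with mean counts of at least 100.

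In leucine-free medium the same genotype contrast asks how the populations differed under starvation. ATF4 and CHOP targets and uORF mRNAs had fewer footprints in KO cells, and immediate early genes had more RNA and footprints. The footprint median was -0.66 (-0.70 to -0.54) for ATF4 and CHOP targets, with 23 of 29 below 0, and -1.25 (-1.37 to -0.99) for uORF mRNAs, with 6 of 11 passing as lower and none as higher. It was 2.09 (1.86 to 2.17) for immediate early genes, with 27 of 27 above 0, and 0.30 for ribosomal proteins. In replete medium the uORF footprint median was -0.12 (-0.25 to 0.02), but 3 of 11 members passed as lower there too. Replete footprint counts in WT and KO cells were 983 and 303 for Ifrd1, 85 and 42 for Ppp1r15a, and 21 and 4 for Ddit3. Without leucine 569 genes passed as higher and 337 as lower in RNA-seq, and 452 and 214 in footprints.

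Atf4 footprints were at -1.31 (-1.44 to -1.19) in KO against WT cells without leucine, while its RNA was at 0.12. Ifrd1 had -2.27 in footprints, Ppp1r15a -1.86 and Ddit3 -1.78. Chac1 had -2.74 in RNA and -3.08 in footprints, Herpud1 -1.55 and -1.54, and Trib3 -1.87 in RNA. Egr4 had 6.05 in RNA, Arc 5.87 and Btg2 4.76, and in footprints Btg2 had 4.79 and Nr4a1 4.42. Pabpc1 footprints stood at 2.68, and those of Tpt1 at 1.77. Grb10 at -7.36, Gas7 at -8.45 and Xdh at -7.39 (-10.71 to -5.80, from 2 counts in KO cells) were again among the lowest in RNA. Hmgcs1, the synthase at the start of the cholesterol pathway, had 1.90 in RNA and 1.67 in footprints, and Insig1, which holds back the sterol regulator SREBP, 1.33 and 1.75. Across 9100 genes, KO against WT ratios in replete and leucine-free medium had a Spearman rho of 0.64 (Pearson r 0.72) in RNA and 0.47 (0.60) in footprints. Beyond 3 SDs of genes of like count there were 281 genes in RNA and 212 in footprints, and 242 higher and 114 lower genes passed in footprints with mean counts of at least 100.

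Lysosomal membrane proteins and v-ATPase subunits had leucine footprint medians of -0.11 in WT and -0.08 in KO cells, with Npc2 at -0.61 in WT and Atp6v0c at -1.12 in KO cells. In KO against WT footprints they were at -0.18 in replete medium, with Atp6ap2 at -0.84 and Lamp2 at -0.76. Autophagy genes had leucine footprint medians of 0.10 and 0.16, with Nbr1 at 0.52 in WT and Atg12 at 1.02 in KO cells. Genes of macropinocytosis and endosome traffic had -0.03 in both genotypes, and 0 of 29 passed in either. Endoplasmic reticulum chaperones had -0.06 and -0.03, with Calr, calreticulin, at -0.36 in WT and -0.85 in KO cells. Aminoacyl-tRNA synthetases had -0.02 and -0.22, with the leucyl synthetase gene Lars at 0.17 and -0.58. Random lists of like expression had -0.14 in KO footprints, and 719 of 10000 lay below the synthetases. Amino acid transporters had 0.13 in WT and -0.16 in KO footprints, and -0.54 (-0.66 to -0.42) in KO against WT cells without leucine.

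Initiation factors had leucine footprint medians of -0.03 in WT and -0.13 in KO cells, ribosome biogenesis factors 0.01 and -0.11, and stalling and rescue factors -0.16 and -0.10. Genes of amino acid sensing and the eIF2alpha kinases, a list that includes Eif2ak4, had 0.08 and 0.06. Sesn2, a leucine-sensing inhibitor of mTORC1 that is also on the list of ATF4 and CHOP targets, stood at 0.82 in WT footprints. Branched-chain amino acid catabolism had -0.10 and -0.33, with Bckdk, the kinase that restrains it, at 0.62 in KO cells. Mitochondrially encoded proteins had 0.19 and 0.21 in footprints, nuclear-encoded oxidative phosphorylation -0.13 and -0.20, S phase genes 0.02 and -0.22, G2 and mitosis genes 0.06 and -0.20, and glycolysis 0.03 and -0.35. In KO footprints random lists of like expression were also below 0, at -0.10 for S phase, -0.13 for G2 and mitosis and -0.11 for glycolysis.

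Duct and epithelial markers had leucine RNA medians of 0.24 in WT and 0.26 in KO cells, and KO against WT medians of 0.81 and 0.87 in replete and leucine-free medium. Krt18 had 59.5 and 105 CPM of RNA in WT cells and 145 and 283 in KO cells. Sox9, a duct and progenitor transcription factor, had RNA CPM of 153 and 187 in WT and 291 and 751 in KO cells. Of the 14 duct and epithelial markers, 8 were measured in RNA. Epcam and Tff1 had 0 RNA counts in every library, and Krt19 had at most 0.595 CPM of RNA. Of the 15 fibroblast and mesenchymal markers, 10 were measured in RNA, with Col3a1 reaching 1870 CPM and Vim between 1080 and 1540. Lum and Thy1 had 0 RNA counts in every library, and Dcn, Pdgfra and Fap had at most 0.548 CPM of RNA. The measured fibroblast and mesenchymal markers had leucine RNA medians of 0.19 and 0.02. Their KO against WT RNA medians were -0.14 and -0.17 in replete and leucine-free medium. Members went both ways in replete medium, with Acta2, smooth muscle actin, at a KO against WT RNA log2 ratio of 2.11 and the collagen gene Col1a1 at -1.71. No acinar and no immune or endothelial marker was measured, and the highest RNA levels were 0.238 CPM for the acinar gene Prss2 and 0.580 for the macrophage gene Cd68.

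RNA and footprint leucine responses were nearly unrelated across the 9100 genes, which are not independent replicates. Spearman rho was -0.08 in WT cells and 0.06 in KO cells (Pearson r 0.03 and 0.29). Between WT and KO cells the leucine responses had a rho of 0.19 in RNA, 0.09 in footprints and 0.15 in TE. RNA and footprint ratios of KO against WT cells had a rho of 0.56 in replete and 0.42 in leucine-free medium, and RNA and footprint WT minus KO differences 0.07. With the KO against WT ratios across media given above these are 10 pairs, described without a test.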

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

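All tests named here were chosen after the patterns had been seen, though for the thinning of footprint reads the bounds were set before the thinned values were computed. The first 3 patterns were picked from the values reported above. The other results drew attention by an opposite sign of the leucine response in WT and KO cells, or by reads in features that the comparisons leave out. None of these differences was tested across cultures, since each group is 1 library.

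In WT cells without leucine, ribosomal protein mRNAs had a TE median of -0.78, against -0.07 in KO cells. RNA ratios fell with gene length in the WT pair, yet the WT minus KO TE median was still -0.44 with the length trend removed. Thinning the other footprint libraries to the protein-coding read total of the WT leucine-free one left WT minus KO footprint medians no higher than -0.33. Thinning adds counting noise only, so it addresses read number and cannot address other ways in which that library may differ. Reads shared between near-identical gene copies go uncounted, and their part cannot be told apart, since the counting interval of the WT minus KO TE median, which ended at -0.51, covers counting error only. Whether another WT culture would show the same also stays open.

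Immediate early genes were higher without leucine in KO cells, in RNA and in footprints. The lower of the RNA and footprint medians was 1.88, and a fault confined to 1 library would not raise both. These medians are the pattern itself, so they are no separate test of such a fault. With 1 library per group, an effect of handling the single culture cannot be told apart from an effect of leucine or genotype, since medium changes alone are known to induce these genes. The RNA-seq and footprint libraries of a group may come from the same dish, which would make their likeness no second culture.

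Many genes differed between KO and WT cells in both media, and genes of chromosomes X and 3 were lower in KO cells as a set. Their footprint median nearest 0 was -0.29, but the chromosomes were chosen by such values, so a chromosome copy number that differs between the populations cannot be told apart from other causes. For single genes, 31% of the genes lower in KO RNA in replete medium lay on chromosomes X, 3 and 5, and the share due to copy number cannot be told apart from the share due to Gcn2 or to separate growth of the populations. No DNA reads were used here, so copy number itself was not measured.

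The immediate early list had a TE difference of 0.48 between genotypes, with medians of 0.30 in WT and -0.25 in KO cells. G2 and mitosis genes had an RNA difference of 0.18, from 0.12 and -0.07, and mitochondrially encoded proteins 0.21, from 0.19 and -0.03. With the length trend removed the WT median of the mitochondrially encoded proteins was -0.07, so its sign was no longer opposite, and random lists matched on expression and length had a WT median of 0.27. Amino acid transporters had a footprint difference of 0.35, from 0.13 and -0.16. The ATF4 and CHOP targets also hold amino acid transporter genes, such as Slc7a11 and Slc38a2, so these may not be separate results.

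Among single genes in RNA, the WT minus KO difference was -3.10 for Cpn1 (-2.09 in WT, 1.01 in KO), 4.05 for Eno1b (1.82 and -2.22), -3.89 for Itgb1bp2 (-2.85 and 1.04) and -3.22 for Zfp607b (-1.64 and 1.59). These rest on few reads. WT replete and leucine-free RNA counts were 15 and 3 for Cpn1, 27 and 94 for Eno1b, 63 and 8 for Itgb1bp2, and 107 and 33 for Zfp607b. The KO counts were 83 and 136, 48 and 8, 28 and 47, and 33 and 81 in the same order. In footprints the difference was 6.83 for Nhlrc1, from 1.41 in WT and -5.42 in KO cells, a gene with no RNA reads in the KO libraries. Nhlrc1 had 858 footprint counts in KO replete cells and 13 in KO leucine-free cells. It had 18 and 13 in WT cells, so the difference rests on the KO replete library.

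In TE the difference was 3.81 for Actg1 (1.27 in WT, -2.55 in KO) and 2.57 for Tpm2 (1.18 and -1.40). It was -2.65 for Fuca1 (-1.56 and 1.09), -2.22 for Hist1h4a (-1.21 and 1.01) and -2.70 for Ndufa6 (-1.45 and 1.26). Nudt21 had -3.14 (-2.06 and 1.09), Odc1 -2.18 (-1.04 and 1.14) and Sec61g -3.61 (-2.46 and 1.16). Several of these differences rest on few reads. In WT replete, WT leucine-free, KO replete and KO leucine-free cells Actg1 had 30, 35, 28 and 161 RNA counts. Its footprint counts were 27, 21, 45 and 36. Tpm2 had 32 and 16 RNA counts in WT cells. In WT leucine-free cells Nudt21 had 7 footprint counts and Sec61g 12. Fuca1 had 1018, 77, 118 and 144 footprint counts in WT replete, WT leucine-free, KO replete and KO leucine-free cells. Its WT value thus rests largely on the WT replete library. Reads shared with other genes go uncounted, and their part was not tested.

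Footprint libraries also held reads outside the genes classed as protein-coding, a larger share without leucine in both genotypes. Mitochondrial tRNA took 2.26% of WT leucine-free footprint reads against 1.91% in replete medium, and 2.07% against 1.46% in KO cells. Mitochondrial rRNA took 2.87% against 2.60% in WT and 2.54% against 1.94% in KO cells. Other rows, of another class or left without a gene class, took 4.07% against 2.90% in WT and 4.04% against 3.00% in KO cells.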

How the results depend on the processing

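No paired analysis was possible because each group is 1 library, and leaving out a library was impossible because each library is a group. Settings with length removal, like-count SDs, footprint genes with RNA, thinned footprint reads and length-matched random lists were chosen after seeing the data. A leucine-codon analysis and its version at mean counts of at least 100 were not run, since no coding sequences were used here. Counts of passing genes follow the order RNA-seq in WT, KO, KO against WT replete, KO against WT leucine-free and WT minus KO, the same for footprints, then TE in WT, KO and WT minus KO. Counts of genes moved by more than 1.5 times in 60 cases and by less in 75. List medians left the counting interval of the median first given in 125 cases, stayed within it in 1819 and reversed in 6. Of the named gene results, 6118 stayed on the same side of the 2-fold rule, 13 came to pass it and 28 no longer did. DESeq2 factors and a prior count of 5 left all 13 gene counts and all 325 list medians within these limits. The low depth of the WT leucine-free footprint library limits single genes of low count.

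With mean counts of at least 10, more genes were tested and more passed. RNA-seq gave 464 in WT, 741 in KO, 1150 in KO against WT replete and 846 in WT minus KO. Footprints gave 210 in WT and 510 in KO against WT replete, and TE 423 in WT and 472 in KO. The ribosomal protein footprint median in KO was 0.08 in place of 0.00; the cause was not tested.

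With mean counts of at least 100, fewer genes were tested and fewer passed. RNA-seq gave 65, 135, 436, 548 and 217, footprints 61, 121, 113, 356 and 235, and TE 119, 109 and 395. ATF4 and CHOP targets had 0.08 in place of 0.29 in WT footprints, and uORF mRNAs 0.48 in place of 0.97 in WT and -0.08 in place of 0.09 in KO footprints. Ribosomal proteins had -0.53 in place of -0.46 in WT and -0.13 in place of 0.00 in KO footprints, and -0.86 in place of -0.78 in WT TE. Immediate early genes had 2.17 in place of 1.88 in KO footprints. The rho of RNA and footprints in WT was -0.12 in place of -0.08. These lists had fewer members; beyond that the cause was not tested.

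With no filter beyond 1 count, RNA-seq gave 893, 1355, 1807, 1853 and 1165. Footprints gave 271 in WT, 342 in KO and 715 in KO against WT replete, and TE 611, 772 and 1098. A 1.5-fold rule is a lower threshold, and gave 708, 967, 1986, 2321 and 1369 in RNA-seq, 644, 993, 1083, 2003 and 1389 in footprints, and 1355, 1446 and 1991 in TE. With all genes tested, RNA-seq gave 363 in WT, 633 in KO and 937 in WT minus KO.

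The rule of 3 SDs of like-count genes is stricter. It gave 66, 110, 235, 281 and 84 in RNA-seq, 91 in WT, 169 and 212 in KO against WT and 134 in WT minus KO for footprints, and 98, 72 and 92 in TE.

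With the length trend removed, ATF4 and CHOP targets had 0.27 in place of 0.13 in WT TE. uORF mRNAs had 0.06 in place of -0.01 in WT RNA and 1.17 in place of 0.87 in WT TE. Ribosomal proteins had 0.09 in place of 0.30 in WT RNA, 0.04 in place of 0.08 in KO RNA and 0.08 in place of 0.17 in WT minus KO RNA, with -0.50 in place of -0.78 in WT TE and -0.44 in place of -0.57 in WT minus KO TE. Other 5' TOP mRNAs had 0.24 in place of 0.28 in WT RNA and -0.53 in place of -0.63 in WT TE. Lysosomal hydrolases had 0.04 in place of 0.08 in WT RNA and -0.05 in place of -0.11 in WT TE. Immediate early genes had 0.57 in place of 0.76 in WT RNA and 0.46 in place of 0.30 in WT TE. Medians that reversed were mitochondrially encoded proteins in WT RNA at -0.07 from 0.19, oxidative phosphorylation in WT minus KO TE at 0.02 from -0.19, ribosome biogenesis in WT TE at 0.01 from -0.06 and amino acid transporters in WT RNA at 0.04 from -0.04. The running medians include the list members themselves, so removal can take away part of a list's own difference. Whether the trend itself is technical was not tested, and the cause was not tested.

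With total counts, uORF mRNAs had 0.11 in place of 0.14 in KO RNA. Other 5' TOP mRNAs had -0.03 in place of 0.00 in KO RNA, 0.30 in place of 0.28 in WT minus KO RNA, -0.19 in place of -0.24 in KO footprints and -0.20 in place of -0.28 in KO TE. Immediate early genes had 2.04 in place of 2.07 in KO RNA. Reversed medians in KO TE were ribosomal proteins at 0.01 from -0.07 and lysosomal membrane proteins and v-ATPase at 0.03 from -0.05. The cause was not tested.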

Other observations

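The tests named in this part were chosen after the results they address had been seen. Genes whose symbols start with Hist were grouped after their values were seen, with no random lists to compare. Among them 48 of 52 were above 0 in WT RNA with a median of 1.02, and 45 in KO RNA with a median of 0.64. These genes are short, with a median exonic length of 595 nt, and the 178 genes under 1000 nt had a WT RNA median of 0.40 as a set. That set includes many of the Hist genes, so it is no separate measure of a length effect. Footprint medians were 0.59 in WT and 0.83 in KO cells, and TE medians -0.47 and -0.02. Most histone mRNAs lack poly(A) tails and rise in S phase, and S phase genes had RNA medians of 0.13 and 0.06. How the RNA-seq libraries were selected is not given in the sources used here.

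Cholesterol genes had an RNA median of 0.19 without leucine in KO cells and 0.00 in WT cells, led in KO by Hmgcs1 at 1.21. In footprints of KO cells Insig1 stood at 1.92 while the list median was -0.02. Glycolysis genes had a TE median of -0.58 in KO cells, with 12 of 13 below 0 and no random list of like expression lower, and -0.11 in WT cells. G2 and mitosis genes had a median of -0.20 in KO footprints, with 24 of 24 below 0, but random lists of like expression had -0.13 and 679 of 10000 were lower. Footprints were measured on 72 genes with a mean RNA count under 30, which took from 0.198% of coding footprints in WT replete to 0.424% in KO leucine-free cells.

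One hypothesis was that mitochondrially encoded footprints, made by ribosomes that eIF2alpha does not control, would serve as a reference for less cytosolic translation in WT cells without leucine. Cytosolic footprints per mitochondrially encoded footprint had log2 ratios of -0.24 in WT and -0.31 in KO cells. The WT minus KO difference was 0.07, so KO cells were as low or lower and the prediction failed. With the RNA ratios taken into account the values were 0.00 in WT and -0.35 in KO cells, so the lower value in WT cells was gone. Only 7 mitochondrially encoded genes were measured, with log2 ratios from -0.21 to 0.48 in WT and from -0.44 to 0.44 in KO cells. Mitochondrial translation itself may differ between the media, which the 0.07 leaves open. Mitochondrial rRNA and tRNA, which are not translated, also took larger shares of footprint reads without leucine in both genotypes, as given above. The ratio therefore cannot tell translation apart from a general difference in mitochondrial reads.

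Another hypothesis was that RNA differences after 1 h are mostly differences between libraries. The higher of the pair of rank correlations of RNA and footprint leucine responses was 0.06, but that low correlation is what prompted the hypothesis and lends it no weight. Translation that offsets RNA differences could also give a value such as 0.06, and with single libraries these cannot be told apart. KO against WT ratios in the same genes had a rho of 0.56 in replete medium.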
